A study of Mus musculus with 35 samples.

How the data were processed

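The series holds 35 mouse libraries: 13 of RNA-seq, 10 of ATAC-seq, 10 of ChIP-seq with input and 2 of ChIA-PET. Groups were taken from the sample names and source descriptions, and all 35 libraries could be placed in a group. The label of 1 e14.5 SN ATAC library differs from the others of its group in the embryonic day and the strain, and it was kept in the group by its title. The processed files combined the libraries of a group into 1 value or 1 list per cell type, so replicates could not be compared, averaged or left out, and nothing in the sources used here says whether replicates came from separate cultures or litters. Read numbers per library were not given in the sources used here, so depth is unknown and no value carries an interval of sequencing error.

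RNA was aligned to mm10 with STAR and abundances were computed with Cufflinks, per the labels' protocols. Ribosomal RNA was removed with Ribo-Zero from cultured cells and with another kit from sorted neurons, which also gave fewer cells, per the labels. The expression columns were deposited as TPM in their header, 1 value per cell type rounded by the authors to whole numbers, and were treated as a score because rounding and the combination of replicates leave no unit to test. The design had been written for FPKM per library and limma; with group values only, log2 ratios were used without a test, which the design also allowed. The table had 20082 lines. A block of 277 lines at its end was shifted: in all 106 of its lines whose symbol (104 symbols) also stands before it, the e10.5 value equalled the earlier e13.5 value, and 37 values of its e13.5 column were below 0 against 0 elsewhere. The first copy of a repeated symbol was kept, and the e10.5 and e13.5 values of the 170 symbols found in the block alone were not used. Per-sample columns left unused numbered 0.

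ATAC and ChIP reads were aligned to mm10 with Bowtie2 and ATAC peaks were called with MACS2, per the labels. Peak names in the 3 lists of sorted neurons show the broad mode of MACS2 on merged replicates. These lists give the MACS2 pileup, a signal, for each peak as deposited, with fold enrichment over local background as a ratio computed by the authors' peak caller. They give p and q values as −log10, also as deposited. The in vitro MN ATAC and Med1 lists give as their deposited score a fixed multiple of the −log10 q, and the H3K27ac list a score of unstated scale. The labels name GEM for ChIP peaks of transcription factors, while the Med1 list has the layout of MACS2. Scores were used only to rank peaks within a list. In the deposited enhancer list, regions carry the name of a Med1 peak (28010) or an H3K27ac peak (3270) and of an ATAC peak, and 67.5% of them overlap an H3K27ac peak. The lists of sorted neurons hold few peaks near promoters, and the filter behind this was not given in the sources used here.

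The gene table gives distances in bp between leftmost coordinates of neighbouring genes, as checked against the mm10 annotation (GENCODE), where 19282 of its 20006 genes were found (96.4%). It has a neighbour on both sides for 19965 genes. Contacts come from RNA polymerase II ChIA-PET, and the caller was not given in the sources used here. Genes skipped by a contact, and regions called intergenic, were judged by protein-coding genes alone. In the progenitor contact table promoter and enhancer stood in swapped order in 1890 of 3895 lines, judged by the sign of the listed distance, and were put back by that sign. Of lines with an annotated gene, 90.2% then had the promoter near the gene's own start, against 46.1% as listed. The Isl1 and Lhx3 table has no header, and a column of whole numbers in it was not used because its meaning is not given. The orthologue table gives intergenic lengths in bp and the deposited log2 of neuronal over non-neuronal expression, by which the authors ranked 500 neuronal and 500 non-neuronal orthologues. The lists of tissue classes named e10_MN, e13_MN and e14_SN are called here the e10.5 MN, e13.5 MN and e14.5 SN classes. Other tissues in these lists come from outside the series.

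Expression was compared as log2((A + 1)/(B + 1)), with a pseudocount of 1 TPM, among genes with at least 1 TPM in either group. A gene was called higher or lower beyond a log2 ratio of 2, that is 4-fold; the ratio understates the change of low genes. For genes listed at 0 in a group no fold is given. The 17 gene lists (367 genes), the gene rule, the tests and most alternatives were fixed before the data were examined. The lists cover pluripotency, motor neuron and sensory neuron identity, pan-neuronal genes, axon guidance, synaptic adhesion, channels, Hox, neural progenitors, cell cycle, housekeeping, other spinal interneurons, glia, endothelium, blood, mesenchyme and muscle. Where a percentile is given, the median of a list was placed among 10000 random lists of the same size matched on mean expression, as a description of these columns.

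The rule for named genes allowed at most 4 examples per list, those with the greatest absolute log2 ratio among called members, plus the 5 genes with the greatest ratios in each direction. Its demand that libraries do not overlap could not be applied. For regulatory comparisons it allowed the 5 highest genes of each class and of the motor neuron, pan-neuronal and pluripotency lists, and for orthologues the 5 greatest ratios and members of the lists. Mnx1, Isl1, Lhx3, Chat, Ntrk3, Pou5f1 and Tubb3 were named where measured. Genes named outside the rule are the ribosomal protein genes and those of the stretches without open sites, which were chosen after their values were seen, and 2 erythroid genes, which were picked for mention from a list that was written before its values were seen.

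Overlaps were counted with bedtools 2.31.1 at 1 bp or more, with 20 shuffles of the peaks within their chromosomes as background. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Gene classes were compared by a two-sided permutation test of the difference of medians with 100000 resamples (smallest p 1e-05) and Benjamini-Hochberg adjustment over the classes of a measure, with bootstrap intervals from 2000 draws. Open sites and enhancers were counted between the transcription starts of the neighbouring protein-coding genes in the annotation. This interval can differ from the distance in the gene table and leave out part of a gene's own body. Intervals of neighbouring genes overlap, so a site can count for several genes. Orthologue lengths were compared between species by a sign-flip permutation test of log2 ratios and between classes by permuting the class. In all these tests genes are the units and not independent replicates, since neighbours and paralogues share values. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, with the random seed 20.

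The tests were first run on simulated data, 200 times each. For interval length over 20006 genes, 6% of runs with no effect gave p below 0.05, a 1.25-fold difference was found in 95.5% and a 1.5-fold difference in 100% of runs. For the share of sites at broad neuronal genes, 3% of null runs passed and a rise of 3 points was found in 98%. For the 3600 orthologues, 6% of null runs of the sign-flip test passed and a mean log2 ratio of 0.2 was found in 99.5%. Genes were independent in the runs of shares and orthologues. Class and other genes drew site numbers alike there, and the sign-flip runs tested means, whereas medians are reported. These rates therefore need not hold for the data.

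Alternatives changed a single choice at a time: a pseudocount of 0.1, no filter or a minimum of 5 TPM, quantile normalization, scaling without haemoglobin and mitochondrial genes, a reciprocal overlap of 50%, the better-scoring 50% of peaks, equal numbers of peaks, sites beyond 5 kb of a start, references matched on expression with 5 genes per class gene, means of log2 values, counts per kb, other definitions of the interval, enhancers within 2 kb, and other sets or scales of orthologues. The values of 2 genes that the rule allowed are not reported here. ChIP input files and separate Isl1 and Lhx3 peaks were not used here.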

Results

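Expression, open chromatin, enhancer marks and enhancer contacts were measured in 35 libraries of mouse cells. Motor neurons (MN), the spinal neurons that drive muscle, were made in culture from mouse embryonic stem cells (mESC) by direct programming, in which doxycycline switches on programming factors together with retinoic acid. The cultures spent 2 days in medium and 2 days under induction and are called in vitro MN here. MN progenitors came from the same stem cells with retinoic acid and an agonist of Hedgehog signalling. Neurons of embryos were sorted by a fluorescent reporter: MN at embryonic day 10.5 (e10.5 MN) by a reporter of Hb9, the product of Mnx1, MN at embryonic day 13.5 (e13.5 MN) by a nuclear reporter of Chat, and sensory neurons at embryonic day 14.5 (e14.5 SN) by a reporter of TrkC, the product of Ntrk3. RNA-seq covered 3 libraries each of mESC, in vitro MN and e10.5 MN and 2 each of e13.5 MN and e14.5 SN. ATAC-seq, which cuts open chromatin with a transposase, covered 2 libraries each of in vitro MN and e13.5 MN and 3 each of e10.5 MN and e14.5 SN. Chromatin immunoprecipitation (ChIP-seq) of Isl1, Lhx3, the Mediator subunit Med1 and the histone mark H3K27ac, with input, covered 2 libraries each in in vitro MN. RNA polymerase II ChIA-PET, which joins pieces of DNA held together at the polymerase, covered 1 library of in vitro MN and 1 of MN progenitors.

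Each measurement reached this comparison as a single value or a single list per cell type, so no spread between replicates could be computed and differences in expression carry no test. The expression table gave 1 transcripts-per-million (TPM) value per gene and cell type, rounded to whole numbers, for 19974 gene symbols. The listed TPM summed to 866563 in mESC, 911859 in in vitro MN, 724454 in e10.5 MN, 654425 in e13.5 MN and 432780 in e14.5 SN, and the number of reads behind them is unknown. Genes listed at 0 numbered 6755, 7105, 6557, 5929 and 8813 in the same order. Across genes, which are not independent replicates, Spearman's rho between TPM columns was 0.731 for mESC and in vitro MN, 0.915 for in vitro MN and e10.5 MN, 0.929 for e10.5 and e13.5 MN and 0.656 for e13.5 MN and e14.5 SN.

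The genes behind the reporters and the cell identities followed the group names. Isl1 and Lhx3 are programming factors of the induction, so their values in in vitro MN do not check identity there. Mnx1, a homeodomain factor of motor neurons, was listed at 2 TPM in mESC, 184 in in vitro MN, 448 in e10.5 MN, 282 in e13.5 MN and 0 in e14.5 SN. Isl1, a LIM homeodomain factor of motor and sensory neurons, stood at 1, 548, 188, 183 and 279 TPM, and Lhx3, its motor neuron partner, at 1, 247, 102, 58 and 2 TPM. Chat, which makes acetylcholine, stood at 0, 111, 13, 16 and 0 TPM. Ntrk3, the neurotrophin receptor of proprioceptive sensory neurons, stood at 0, 18, 9, 38 and 364 TPM. Pou5f1, a core pluripotency factor, stood at 732 TPM in mESC, 1 in in vitro MN and 0 in the 3 sorted groups. Tubb3 expression was not analysed here.

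**Figure D1:**
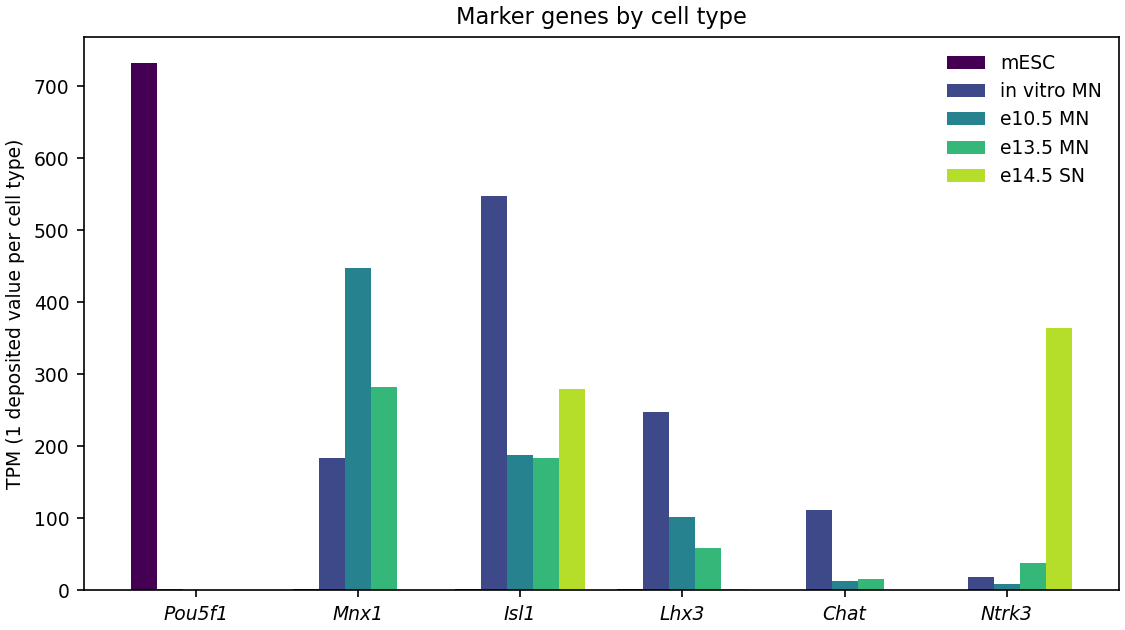
Bars give the TPM (vertical axis, linear from 0) of 6 marker genes (horizontal axis) in each of the 5 cell types (colours), as a single deposited value per cell type with no error. Mnx1 stands at 448 TPM in e10.5 MN and 0 in e14.5 SN, and Ntrk3 at 364 TPM in e14.5 SN against 38 in e13.5 MN.

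To describe what direct programming changed, in vitro MN were set against mESC. Most genes of the motor neuron, axon guidance and Hox lists stood far higher in in vitro MN, and pluripotency genes far lower. Slit2, a secreted guidance cue, was listed at 2541 against 6 TPM (log2 ratio 8.50), Isl1 at 548 against 1 (8.10) and Isl2, its close relative, at 355 against 1 (7.48). The rise of Isl1, a programming factor, is part of the induction itself. Tdgf1, a Nodal co-receptor of early embryos, stood at 1 against 849 TPM (-8.73), Pou5f1 at 1 against 732 (-8.52) and Nanog, another pluripotency factor, at 1 against 504 (-7.98). Of 14215 genes compared, 1734 were more than 4-fold higher in in vitro MN and 789 more than 4-fold lower, so 68.7% of these calls were higher. Quantile normalization across cell types moved the split to 1282 higher and 1077 lower, or 54.3%, and shifted the median log2 ratio of all genes, 0.30 as deposited, by -0.39. Medians of gene lists are therefore given as the difference from the median of all genes, and the log2 ratios of single genes as deposited on the log2(TPM + 1) scale.

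Motor neuron identity genes were higher by more than 4-fold for 18 of 20 members compared, with a median 5.42 above that of all genes. Among them are the programming factors Isl1 and Lhx3, which the induction itself switches on. Lhx4, another LIM homeodomain factor, stood at 210 TPM and was listed at 0 in mESC. Pan-neuronal genes were higher for 37 of 42 members (3.40), among them Elavl4, an RNA-binding protein of neurons, at 304 against 1 TPM (7.25), Gap43, a growth cone protein, at 593 against 3 (7.21), Nefl, a neurofilament subunit, at 1516 against 10 (7.11), and Dcx, a microtubule binder of young neurons, at 375 TPM and listed at 0 in mESC. Hox genes, which set position along the body axis, were higher for 15 of 22 members (5.28): Hoxb6 at 261, Hoxd3 at 240, Hoxb2 at 202 and Hoxb3 at 171 TPM, all listed at 0 in mESC. Axon guidance genes were higher for 22 of 27 members and lower for 1 (3.82), with the semaphorin Sema6a at 244 against 1 TPM (6.94) and Dcc, a netrin receptor, at 108 TPM and listed at 0 in mESC. Synaptic adhesion genes were higher for 16 of 27 members (2.50), with the neurexin gene Nrxn3 at 41 TPM and listed at 0 in mESC. Channel genes were higher for 14 of 27 members (2.50), with the acetylcholine receptor subunits Chrna3 at 260 and Chrna4 at 73 TPM against 0 and 1. Neural progenitor genes were higher for 13 of 19 members (2.74); Fabp7, a radial glial fatty acid binder, stood at 196, Hes5, a Notch target, at 184 and Neurog2, a proneural factor, at 133 TPM, all listed at 0 in mESC.

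Pluripotency genes were lower by more than 4-fold for 22 of 25 members, with a median -6.64 from that of all genes and Dppa5a at 8 against 2772 TPM (-8.27). Cell cycle genes gave no call in 20 members, yet their median lay -1.04 from that of all genes and at percentile 0.01 among 10000 random lists matched on mean expression. Sensory neuron genes were higher for 7 of 17 members (0.70, percentile 93.1), with the sodium channel Scn9a at 23 TPM and listed at 0 in mESC. Housekeeping genes were higher for 1 of 27 members, other spinal interneuron genes higher for 1 and lower for 1 of 8, and glial genes higher for 1 and lower for 2 of 6. Endothelial genes were lower for 2 of 5, mesenchymal genes for 2 of 9, muscle genes for 3 of 6, and blood genes gave no call in 3. Outside the lists, Cyp26b1, which degrades retinoic acid, stood at 293 TPM and was listed at 0 in mESC.

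To compare neuron types, e13.5 MN were set against e14.5 SN. More members of the motor neuron, Hox and progenitor lists were called higher than lower in e13.5 MN, and more members of the sensory neuron list higher in e14.5 SN. Mnx1 at 282 TPM and Slit3, a guidance cue, at 199 TPM were listed at 0 in e14.5 SN. Avil, an actin binder of sensory neurons, stood at 2 against 205 TPM (-6.10) and Etv1, an ETS factor of proprioceptive neurons, at 8 against 145 (-4.02). Of 14115 genes compared, 3935 were more than 4-fold higher in e13.5 MN and 521 lower (88.3% higher). That split depended on scale: after scaling to the same sum without haemoglobin and mitochondrial genes it was 3713 and 1068 (77.7%), and after quantile normalization 1932 and 1721 (52.9%). The median log2 ratio of all genes was 1.13 and moved by -0.30 and -0.98 under these scalings, so list medians are again given relative to it.

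The 2 columns also differed in markers of other cell types and in RNA composition, which stand beside every gene group of this comparison. Haemoglobin genes held 1.51% of the listed TPM in e13.5 MN and 0.000462% in e14.5 SN, with the embryonic globin Hbb-y the highest gene of the e13.5 column at 6204 TPM. Markers of endothelium were more than 4-fold higher in e13.5 MN for 8 of 8 members (3.20 above all genes), for example Cldn5, a tight junction protein, at 104 TPM and listed at 0 in e14.5 SN. Markers of blood were higher for 7 of 12 (3.71), of mesenchyme for 8 of 10 (1.42), of muscle for 6 of 7 (2.52) and of glia for 6 of 10 with 1 lower (1.65). Col3a1, a fibrillar collagen, stood at 71 against 2 TPM (4.58), the titin gene Ttn at 43 against 1, and S100b, a glial calcium binder, at 3 against 71 (-4.17). After quantile normalization these counts were 7 of 8, 6 of 12 with 1 lower, 4 of 10, 5 of 7 and 3 of 10 with 1 lower. Most blood calls were haemoglobin genes, and the scaling that leaves these out gave 2 blood markers higher and 1 lower. Mitochondrial genes held 6.93% of the listed TPM in e14.5 SN and 0.821% in e13.5 MN. The ribosomal protein genes Rps29 and Rps21 were listed at 0 in e14.5 SN, against 889 and 792 TPM in e13.5 MN, as were 10 of 81 such genes in all. Every cell uses these genes, so a 0 in this column may be a missing estimate and is not read here as absence. Markers of other cell types were also listed at 0 in 1 of the 2 columns, from 2 of 10 mesenchymal to 9 of 12 blood members.

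Motor neuron identity genes were higher in e13.5 MN for 12 of 20 members and lower for 1 (1.58 above all genes, 10 higher after quantile normalization). Hox genes were higher for 22 of 28 (2.16, 14 after quantile normalization), with Hoxd3 at 149 against 1 TPM (6.23) and Hoxb9 at 223 against 3 (5.81). Axon guidance genes were higher for 14 of 27 (0.90), which became 7 higher and 2 lower after quantile normalization. Among them, Nrp2, a semaphorin receptor, stood at 110 against 6 TPM (3.99), Efnb3, an ephrin, at 48 against 1 (4.61) and the chemokine receptor Cxcr4 at 112 TPM and listed at 0 in e14.5 SN. Neural progenitor genes were higher for 19 of 20 (4.26, 16 after quantile normalization) and cell cycle genes for 18 of 20 (3.45, 14 after it), in the column where the endothelial and blood markers were also higher. Nes, an intermediate filament of progenitors, stood at 230, Hes5 at 144, Top2a, a topoisomerase of dividing cells, at 180 and Cdk1, a mitotic kinase, at 89 TPM, all listed at 0 in e14.5 SN. Housekeeping genes were higher for 10 of 27 and lower for 1 (0.43, 5 higher after quantile normalization), with the ribosomal protein genes Rplp0 at 1010 against 114 TPM (3.14) and Rpl13a at 1353 against 159 (3.08). Other spinal interneuron genes were higher for 11 of 17 (1.87, 10 after quantile normalization), with the paired-box factor Pax2 at 47 TPM and listed at 0 in e14.5 SN. All 17 interneuron genes compared, and 14 of the 20 progenitor genes, were listed at 0 in 1 of the 2 columns, so these calls and medians rest largely on listed zeros. Pluripotency genes were higher for 5 of 10 (0.75), led by Sox2, which progenitors also use, at 108 against 2 TPM.

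Sensory neuron identity genes were lower in e13.5 MN for 10 of 24 members and higher for 5, with a median -2.56 from that of all genes; after quantile normalization 16 were lower and 2 higher. Pan-neuronal genes were lower for 7 of 41 and higher for 1 (-1.73), among them Cplx1, a synaptic vesicle regulator, at 16 against 342 TPM (-4.33) and Nefm, a neurofilament subunit, at 552 against 5922 (-3.42). The call of Nova1, a neuronal splicing factor at 50 TPM, as the member that was higher rests on a listed 0 in e14.5 SN. Synaptic adhesion genes were lower for 3 of 29 and higher for 2 (-1.28), with Cntnap2 at 18 against 165 TPM (-3.13); after quantile normalization 12 were lower and 0 higher. Channel genes were higher for 5 and lower for 4 of 31 (-0.54), a balance that quantile normalization turned to 2 higher and 7 lower. Of these, Kcna1, a potassium channel, stood at 4 against 55 TPM (-3.49). The lowest ratios outside the lists included the signalling adaptor Shc4 at 5 against 938 TPM (-7.29) and Zdhhc22 at 1 against 293 (-7.20).

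To ask how far cultured MN matched embryonic ones, e10.5 MN were set against in vitro MN. More members of the Hox and progenitor lists were called higher than lower in e10.5 MN, and more members of the channel list higher in culture. Hoxc6 at 255, Hoxa9 at 113, Hoxc9 at 81 and Hoxc10 at 76 TPM in e10.5 MN were listed at 0 in in vitro MN. Olig2, the factor of motor neuron progenitors, stood at 147 against 1 TPM (6.21). Chat stood at 13 against 111 TPM (-3.00) and Slc5a7, the choline transporter, at 4 against 35 (-2.85). Of 13742 genes compared, 183 were more than 4-fold higher in e10.5 MN and 347 lower (34.5% higher); the split was 295 and 313 (48.5%) after scaling to the same sum, and 276 and 228 (54.8%) after quantile normalization. The median log2 ratio of all genes was -0.24 and moved by 0.29 and 0.24 under these scalings. With a pseudocount of 0.1 the counts were 1078 and 894. The kit that removed ribosomal RNA and the number of cells also differed between cultured and sorted cells, so kit and origin cannot be told apart here.

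Hox genes were higher in e10.5 MN for 13 of 28 members and lower for 1, with a median 0.95 above that of all genes. Neural progenitor genes were higher for 7 of 20 and lower for 1 (1.33), with the proneural factors Neurog1 at 76 against 2 TPM (4.68) and Neurod4 at 99 against 4 (4.32). Markers of other spinal interneurons were higher for 4 of 16 (1.54), for example En1 at 13 TPM and listed at 0 in culture, and glial markers for 3 of 9 (1.24), with the neural crest factors Foxd3 at 32 and Sox10 at 17 TPM, both listed at 0 in culture. Motor neuron identity genes were higher for 2 and lower for 3 of 20 (-0.38). Of these, Aldh1a2, which makes retinoic acid, stood at 79 TPM and was listed at 0 in culture, and the factor Ebf2 stood at 41 against 6 (2.58). Channel genes were lower for 7 of 27 (-0.76), with Gria2, a glutamate receptor subunit, at 2 against 23 TPM (-3.00) and Chrna3 at 35 against 260 (-2.86). Synaptic adhesion genes were lower for 4 of 28 and higher for 1 (-0.34), and sensory genes lower for 4 and higher for 2 of 17 (-0.68). Pan-neuronal genes were higher for 1 and lower for 1 of 41 (-0.51), with the repressor Scrt2 at 142 against 8 TPM (3.99), and axon guidance genes lower for 2 of 27 (0.11). Pluripotency genes were lower for 2 of 19 (-0.76) and mesenchymal genes for 1 of 8, while cell cycle (20 compared), housekeeping (27), endothelial (4), blood (4) and muscle genes (5) gave no call. Small counts moved with scale: after scaling to the same sum, and then after quantile normalization, synaptic adhesion genes had 2 higher and 2 lower, then 1 and 1, axon guidance genes 1 and 0, then 0 and 1, and sensory genes 3 and 4, then 3 and 3. Under both scalings interneuron genes had 7 higher, and pan-neuronal and mesenchymal genes 1 higher and 0 lower, and Hox genes had 13 higher and progenitor genes 7, as before scaling. Of the members compared, 8 of 28 Hox genes and 12 of 16 interneuron genes were listed at 0 in 1 of the 2 columns; as 2 of 81 ribosomal protein genes are at 0 in in vitro MN too, such zeros are not read as absence. Cyp26b1 stood at 1 against 293 TPM (-7.20), and Plagl1, an imprinted zinc finger gene, at 157 TPM and listed at 0 in culture.

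To see which open chromatin the cell types share, the ATAC peak lists were overlapped, counting any overlap of at least 1 bp. In e10.5 MN, 51.7% of open sites were also open in in vitro MN, 37.8% in e13.5 MN and 44.9% in e14.5 SN. Among sites of e13.5 MN, 54.0% were open in e14.5 SN, 39.1% in in vitro MN and 35.4% in e10.5 MN. The lists held 160906 sites in in vitro MN, 73406 in e10.5 MN, 76743 in e13.5 MN and 129493 in e14.5 SN, with median widths of 565, 287, 354 and 579 bp. With the 73406 best-scoring peaks of each list, the share of e10.5 MN sites open elsewhere was 41.5% for in vitro MN, 37.0% for e13.5 MN and 32.6% for e14.5 SN, so the order of the last 2 turned. At equal numbers 40.7% of e13.5 MN sites were open in e14.5 SN, 28.3% in in vitro MN and 36.2% in e10.5 MN, so the order of the last 2 turned here too.

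Sites overlapped far more than after shuffling along their chromosomes, 15.5 times the shuffled share for e10.5 MN sites in e13.5 MN, 9.28 times for e13.5 MN sites in e14.5 SN, 8.32 times for e10.5 MN sites in e14.5 SN and 7.42 times for e10.5 MN sites in in vitro MN. Exact Clopper-Pearson 95% intervals, which cover counting error only, were 51.3% to 52.0%, 37.4% to 38.1% and 53.6% to 54.3% for the shares of 51.7%, 37.8% and 54.0%. Sites lay mostly beyond 5 kb of a transcription start, 82.7% in in vitro MN, 88.5% in e10.5 MN, 92.0% in e13.5 MN and 90.2% in e14.5 SN. Within 1 kb of a start lay 7.45%, 2.88%, 2.27% and 2.40%, so the lists of the sorted neurons held few promoters. These 3 lists also held 0 sites in a stretch of 8.31 Mb on chromosome 2 (90373514 to 98681147, mm10) and of 3.78 Mb on chromosome 17 (36114625 to 39893062), where in vitro MN had 634 and 156 sites.

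**Figure D2:**
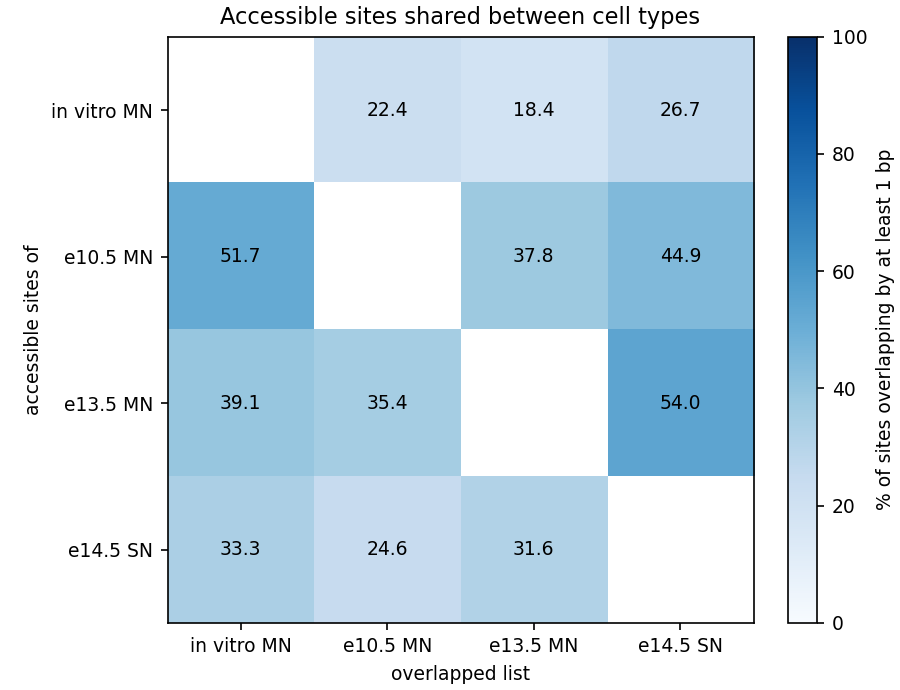
Percent of the open sites of each cell type (vertical axis) that overlap by at least 1 bp an open site in the list of another (horizontal axis), with darker blue for a higher percent. The highest share is 54.0%, for e13.5 MN sites open in e14.5 SN, whose lists differ in length; with equal numbers of peaks it is 41.5%, for e10.5 MN sites open in in vitro MN.

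To find which open sites of in vitro MN carry enhancer marks, ATAC sites were overlapped with Med1 and H3K27ac peaks. Med1 lay at 17.2% of sites and H3K27ac at 13.8%, against 2.18% and 2.77% after shuffling, and 11.2% had both. Within 1 kb of a transcription start the shares were 60.1% and 58.7%, and beyond 5 kb 12.9% and 9.16%. Conversely, 73.7% of 36331 Med1 peaks and 68.5% of 29113 H3K27ac peaks lay on an open site. Of the open sites beyond 5 kb, those with both marks were also open in e10.5 MN in 73.9% of 9343 cases, those with 1 mark in 56.5% of 10688 and those with neither in 17.3% of 113004. The same classes were open in e13.5 MN in 45.9%, 36.9% and 17.1% and in e14.5 SN in 49.5%, 45.9% and 26.2%. The deposited enhancer list held 31280 regions, of which 45.6% were open in e10.5 MN, 27.9% in e13.5 MN and 32.1% in e14.5 SN. Of these regions 25.7% lay within 1 kb and 36.0% within 5 kb of a transcription start. As the lists of sorted neurons held few sites near starts, this may lower the shares.

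To ask whether genes of neurons lie in larger regulatory territories, the deposited interval from the upstream to the downstream neighbour, which runs between leftmost coordinates of genes, was compared between gene classes. Neuronal classes had longer intervals. Genes of the e13.5 MN class had a median interval of 362609 bp (95% bootstrap interval 317891 to 428832) against 98164 bp for other genes, 3.69 times as long, and those of the e14.5 SN class 303712 bp (3.09 times). Genes of the e10.5 MN class had 223839 bp (185086 to 265790, 2.27 times) and broad neuronal genes, used by many neuron types, 269020 bp (227997 to 304224, 2.74 times). With all annotated gene types as neighbours these ratios were smaller, 2.01 for e13.5 MN, 1.85 for e14.5 SN, 1.49 for e10.5 MN and 1.66 for broad neuronal genes (adjusted p = 1.9e-05 each, permutation test). Genes with long intervals included Pcdh7 and Pcdh9, protocadherins, 7810 and 7417 kb, Lrrc4c, a netrin-G ligand, 7150 kb, and Cdh8, a cadherin, 6769 kb. Others were Flrt2, a transmembrane guidance protein, 6396 kb, Ncam2, an adhesion molecule, 5765 kb, and Epha7, an ephrin receptor, 5640 kb. Among fixed lists, Nova1 had 4530 kb, Gap43 2923 kb, Slit2 2675 kb and Isl1 1766 kb, while Lhx3 had 154 kb, Mnx1 135 kb, Chat 85.9 kb, Pou5f1 42.6 kb and Tubb3 35.9 kb. Ntrk3 had 2364 kb.

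All 10 neuronal classes exceeded other genes, by 1.76 times (cortical plate) to 3.69 times, each with adjusted p = 1.58e-05 in a two-sided permutation test of the difference of medians over 19 classes; the raw p of 1e-05 is the smallest that the permutations can give. Of 9 non-neuronal classes, 7 had shorter intervals, from 0.602 times in stomach to 0.826 times in kidney (adjusted p = 0.0106), with heart at 0.778 times (adjusted p = 0.00172). Fewer were shorter under other definitions of the interval, 5 of 9 with annotated gene starts and 4 of 9 over gaps between gene bodies, and with all annotated gene types as neighbours kidney (1.00 times, adjusted p = 1) and heart (0.943 times, adjusted p = 0.373) did not pass the permutation test. Genes of mESC (1.04 times, adjusted p = 0.62) and liver (0.900 times, adjusted p = 0.156) did not pass. The tissue classes are lists that the study ranked, partly on these cells, and that share genes with each other, and a gene is the unit of the test, not a replicate of the experiment. Gene bodies were also longer in all 10 neuronal classes, 1.68 to 4.24 times.

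**Figure D3:**
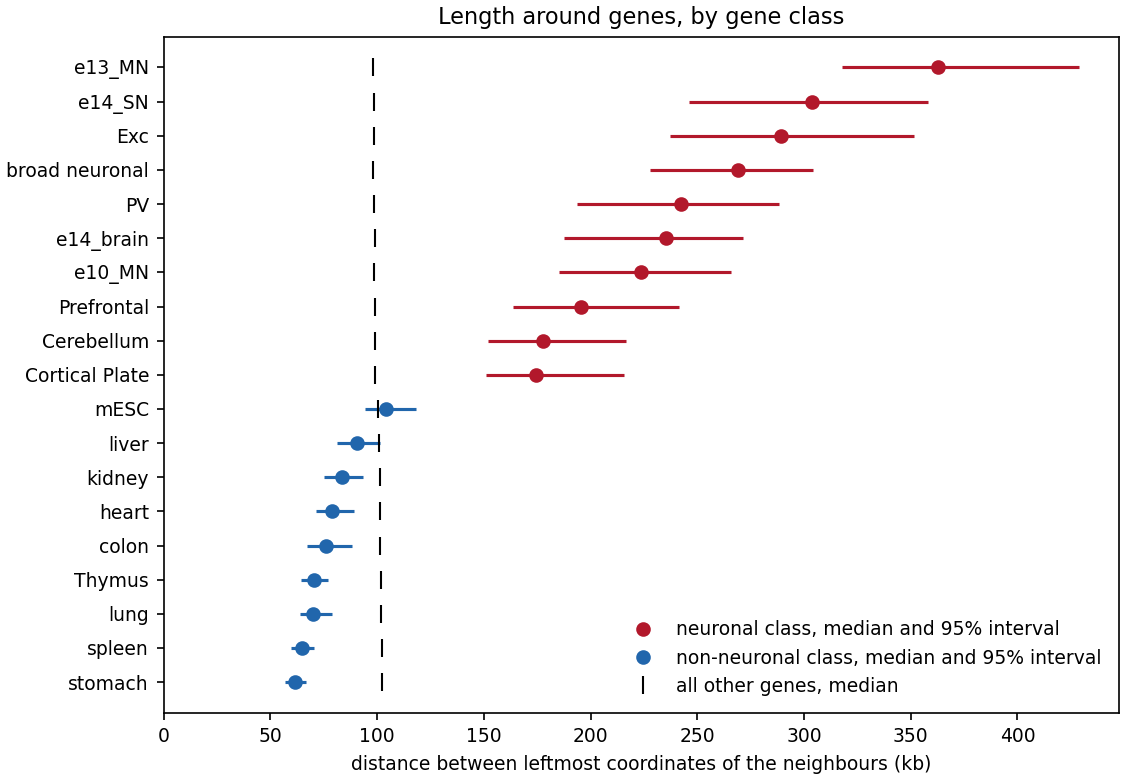
Points give the median interval between the leftmost coordinates of neighbouring genes (horizontal axis, kb) of each gene class (vertical axis, named as in the deposited lists), bars 95% bootstrap intervals and dashes the median of all other genes. The 10 neuronal classes, in red, lie to the right of the dashes, and the e13.5 MN class reaches 362609 bp.

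More open sites lay in the intervals of neuronal genes. Genes of the e13.5 MN class had a median of 10 open sites in e13.5 MN (95% interval 8 to 13) against 1 for other genes, those of the e10.5 MN class 11 against 2 in e10.5 MN, and those of the e14.5 SN class 20 against 3 in e14.5 SN. The roundabout receptor gene Robo2 had 229 sites in e10.5 MN and Zfp608, a zinc finger gene, 164. Flrt2 had 250 and Pcdh9 223 in e13.5 MN, and Pcdh7 344 and Cdh8 303 in e14.5 SN. Isl1 had 97, 92, 128 and 168 sites in e10.5 MN, e13.5 MN, e14.5 SN and in vitro MN, Slit2 97, 109, 171 and 233, Mnx1 5, 3, 3 and 13, and Pou5f1 2, 1, 2 and 1. In each of the 4 lists all 10 neuronal classes had more sites than other genes, with medians of 7 to 15 against 2 in e10.5 MN, 4 to 10 against 1 in e13.5 MN and 10 to 24 against 3 in e14.5 SN. Sites per kb were also higher in all 10, by 1.16 to 2.14 times (on the mean log2 scale in 4 of 10 for in vitro MN and 10 of 10 for the sorted neurons), and in e10.5 MN in 7 of 9 non-neuronal classes as well, by up to 1.21 times. Across 19282 genes, which are not independent replicates, Spearman's rho of interval length and open sites was 0.760 to 0.820. The deposited counts of DNase-hypersensitive and conserved elements were higher in the 10 neuronal classes too, with medians of 44 to 91 and 17 to 36 per gene.

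Enhancers of in vitro MN were counted in the same intervals as the open sites. The counts include regions near transcription starts, as 25.7% of the deposited list lay within 1 kb of a start. Genes of the e13.5 MN class held a median of 7 enhancers, those of the e10.5 MN class 5, and those of the e14.5 SN and broad neuronal classes 4, against 1 for other genes. Robo1 held 99 enhancers, Zfp608 93, Robo2 87, Tenm2, a teneurin adhesion gene, 77, and Meis1, a Hox cofactor, 73. Slit2 held 61, Gap43 54, Isl1 39, Nrg1, a growth factor of the neuron-glia axis, 39, Ntrk3 20, Mnx1 8, Lhx3 2 and Pou5f1 0. The count was higher in 9 of 10 neuronal classes (adjusted p = 2e-05 each, permutation test), with cortical plate genes at 2 and adjusted p = 0.103, and in 0 of 9 non-neuronal classes. Per kb, 5 neuronal classes stood higher, led by the e10.5 MN class at 1.89 times and the e13.5 MN class at 1.55 times; on the mean log2 scale 1 of 10 was higher and 2 were lower. The classes named PV and Exc in the deposited lists stood lower per kb, at 0.805 and 0.769 times; these lists share 352 genes and are not 2 separate results.

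Contacts of promoters with enhancers in in vitro MN were found for 44.2% of e10.5 MN class genes, 37.1% of e13.5 MN class genes, 28.4% of broad neuronal genes and 25.3% of e14.5 SN class genes. The share was 10.9% of mESC class genes, 1.63% of liver and 0.607% of colon genes. Every measured gene with such a contact stood at 2 TPM or more in in vitro MN. Genes silent in these cells may thus be missing by selection, so shares and counts of contacts may partly restate expression. Most genes of every tissue class had no contact, so each class median was 0 and the planned test of medians found no difference. On the mean log2 scale 8 of 10 neuronal classes had more contacts in in vitro MN and 8 of 9 non-neuronal classes fewer, whereas in progenitors 4 of 10 neuronal classes had more and 4 fewer. How the study chose the lists named top500_MN and top500_pMN is not given in the sources used here; 84.2% of the genes of the first had a contact in in vitro MN and 100% of the second in progenitors, so the lists may not be independent of the contacts. Spearman's rho of interval length and contacts was 0.156 across genes.

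To ask whether genes shared by motor and sensory neurons use different open sites in each, sites near broad neuronal genes were split into those open in e13.5 MN, in e14.5 SN or in both. Pcdh7 had 99 sites in e13.5 MN alone, 230 in e14.5 SN alone and 116 in both, Flrt2 149, 185 and 101, and Robo2 47, 233 and 60. Broad neuronal genes (487 genes, 24450 sites) had 50.2 sites per gene against 14.8 for the other 18795. Intervals of neighbouring genes overlap, so these are pairs of a gene and a site, and the same site can count in both sets. Of their sites 76.6% were open in 1 of these 2 cell types, against 74.8% near other genes, a difference of 1.81 points (95% interval 0.784 to 2.94, adjusted p = 0.0349, permutation of the class over genes). Sites of e14.5 SN alone made up 56.9% against 53.4% (3.48 points, interval 1.54 to 5.53, adjusted p = 0.0349). Sites of e13.5 MN alone made up 19.7% against 21.4% (-1.67 points, interval -3.09 to -0.326, adjusted p = 0.0999). With the same number of top peaks from both lists, the difference for sites open in 1 of the 2 cell types was 1.17 points with p = 0.151 in the permutation test. How the study chose the broad neuronal list is not given in the sources used here, so it may not be independent of these cells.

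To compare enhancer contacts between cell types, the contact tables of in vitro MN and MN progenitors were set side by side, each from 1 library and so without a test. In vitro MN came from direct programming and progenitors from retinoic acid with a Hedgehog agonist. Stage and protocol therefore cannot be told apart in any difference between them. Of 21 motor neuron identity genes, 11 had a contact in in vitro MN, 9 of them with 0 in progenitors and 2 with contacts in both. Mnx1 had 5, Isl1 7 and Chat 7, each with 0 in progenitors, while Olig2 had 5 in progenitors and 0 in in vitro MN. Olig2 and Pou5f1 stood at 1 TPM in in vitro MN, and every measured gene with a contact there at 2 TPM or more. Their lack of contacts there may therefore follow from how the list was chosen. The contacts of Mnx1 (chromosome 5, 29473034 to 29478470, mm10) joined intergenic regions at 29480800 to 29487841 and 29466936 to 29470233, and 3 regions in introns of its neighbour Ube3c at 135, 172 and 177 kb. Isl1 (chromosome 13, 116298281 to 116309689) was joined to 7 intergenic regions 180 to 630 kb away, the farthest at 115679503 to 115679837. No protein-coding gene started between them and Isl1, and intergenic here means outside protein-coding genes. Chat (chromosome 14, 32408203 to 32465989) was joined to 2 regions in its own intron and 5 in introns of Parg, 218 to 241 kb away across 3 starts of protein-coding genes. Ntrk3 was joined to 1 region in its own intron (chromosome 7, 78598179 to 78598552), and Lhx3, Pou5f1 and Tubb3 had no contact.

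The most contacts in in vitro MN belonged to Zfp608 with 27, Sox4, a factor of young neurons, with 23, and Klf7, a zinc finger factor, and Irx3, a homeodomain factor, with 19. From the fixed lists, Ebf1 and Foxp1, a determinant of limb motor neurons, had 9, Slit2 5, the adhesion molecule gene Ncam1 13, Elavl4 12, Nefl 11, Gap43 8 and Nova1 6. In progenitors, Sox2 had 8 contacts against 4 in in vitro MN, and Sall4, a pluripotency gene, 6 against 1. Hoxb3 had 12 against 3, but 9 of the 12 overlap the 3, which are wider, so its counts differ partly by how regions were cut. In vitro MN had 4936 gene-enhancer pairs of 2512 genes and progenitors 3814 of 2249. The median distance was 127.1 kb in in vitro MN and 92.4 kb in progenitors, with 57.8% (Clopper-Pearson 95% interval 56.4% to 59.2%) and 47.6% (46.0% to 49.2%) beyond 100 kb. The start of another protein-coding gene was skipped by 41.5% (40.1% to 42.9%) and 50.8% (49.1% to 52.4%) of contacts. Of the pairs, 12.8% (11.9% to 13.7%) and 18.4% (17.2% to 19.7%) were shared. That count rests on putting back 1890 anchors listed in swapped order in the progenitor table. As listed, the shares were 7.46% and 12.5%. Genes with a contact in both cell types numbered 948, and of their pairs 28.2% and 36.3% were shared. The deposited enhancer list of in vitro MN held 98.5% of enhancers in MN contacts and 60.6% of those in progenitor contacts. The shares may thus partly reflect which genes and regions entered each list. Enhancers in MN contacts were open in e10.5 MN in 73.2%, in e13.5 MN in 45.7% and in e14.5 SN in 55.3% of cases, and those in progenitor contacts in 86.4%, 53.3% and 50.6%.

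To relate binding of Isl1 and Lhx3 to expression, genes of the deposited table of Isl1 and Lhx3 bound interactions were compared with other genes that had a contact in in vitro MN. The lowest log2 ratio of in vitro MN to mESC of a gene in the table was 1.00, so the table was chosen on expression. Genes that fell, stayed level or rose less could not enter it, and its higher median is not independent evidence. The table held 10 of 11 motor neuron identity genes with contacts, including Isl1, Mnx1 and Slit2, and 12 of 17 pan-neuronal ones. Its 551 genes measured in both tables had a median log2 ratio of in vitro MN to mESC of 3.03 against 0.39 for 1930 others. The difference was 2.64 (95% bootstrap interval 2.40 to 2.88) with p = 1e-05 in a two-sided permutation test, the smallest p it can give. Against the 504 other contact genes at or above that ratio, the difference was 1.44 (1.19 to 1.68, p = 1e-05 in the permutation test). The table held 1197 interactions of 556 genes with 1105 enhancers.

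To follow intergenic length through evolution, the deposited lengths of 3600 orthologues were compared in 7 species. In mouse, neuronal orthologues had a median of 68.0 kb (95% interval 55.9 to 77.7) against 30.3 kb (23.6 to 34.7) for non-neuronal ones, 2.25 times as long, and in human 79.3 against 34.2 kb (2.32 times). In zebrafish they had 17.9 against 12.1 kb (1.48 times) and in the pufferfish Fugu 7.27 against 5.67 kb (1.28 times). Isl1 lay in 1753 kb in mouse, 1930 in human, 319.8 in zebrafish, 44.6 in Fugu, 35.3 in Drosophila, 10.3 in C. elegans and 17.0 in the tunicate Ciona. Celf4, a neuronal RNA-binding protein, had 4529, 4400, 479 and 178 kb in the vertebrates and was listed at 0 in Drosophila, and Nova1 had 4184, 3562, 16.0 and 28.8 kb, with 0.693 kb in Drosophila. Pou5f1 had 33.4, 88.0, 16.3 and 3.47 kb, with 144 kb in Drosophila, and Isl2 30.1 kb in mouse and 88.9 kb in Fugu.

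The difference between 500 neuronal and 500 non-neuronal orthologues passed a two-sided permutation test in mouse and human (adjusted p = 3.5e-05 each), zebrafish (adjusted p = 0.000933) and Fugu (adjusted p = 0.0128). It did not in Drosophila (0.852 against 0.979 kb, 0.870 times), C. elegans (2.71 against 3.12 kb, 0.869 times) or Ciona (3.92 against 3.64 kb, 1.08 times), each with adjusted p = 0.37. Orthologues in neither set had a lower median than both sets in every species. Theirs was 534 bp in Drosophila, 1206 bp in C. elegans and 3147.5 bp in Ciona, without a test. The lack of a difference between the sets there thus does not show that neuronal orthologues are no longer than orthologues at large. As a mean of log2 lengths the difference between the sets was 0.92 in zebrafish (adjusted p = 0.0781) and 0.44 in Fugu (adjusted p = 0.104) and no longer passed. Lengths listed at 0, of which zebrafish had 325 and Fugu 71, entered these means as a log2 of 0 and can weigh heavily on them. Over all orthologues, the median log2 ratio of mouse to other species was -0.15 for human, 1.47 for zebrafish, 2.53 for Fugu, 3.27 for Ciona, 4.497 for C. elegans and 5.25 for Drosophila, each with p = 1e-05 in a sign-flip permutation test, the smallest it can give. Spearman's rho of lengths across orthologues was 0.827 for mouse and human and at most 0.313 for every other pair of species. The study ranked the neuronal and non-neuronal orthologues by expression, and paralogues can share their invertebrate lengths, so that keeping 1 gene per set of such lengths leaves 2820 of the 3600.

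**Figure D4:**
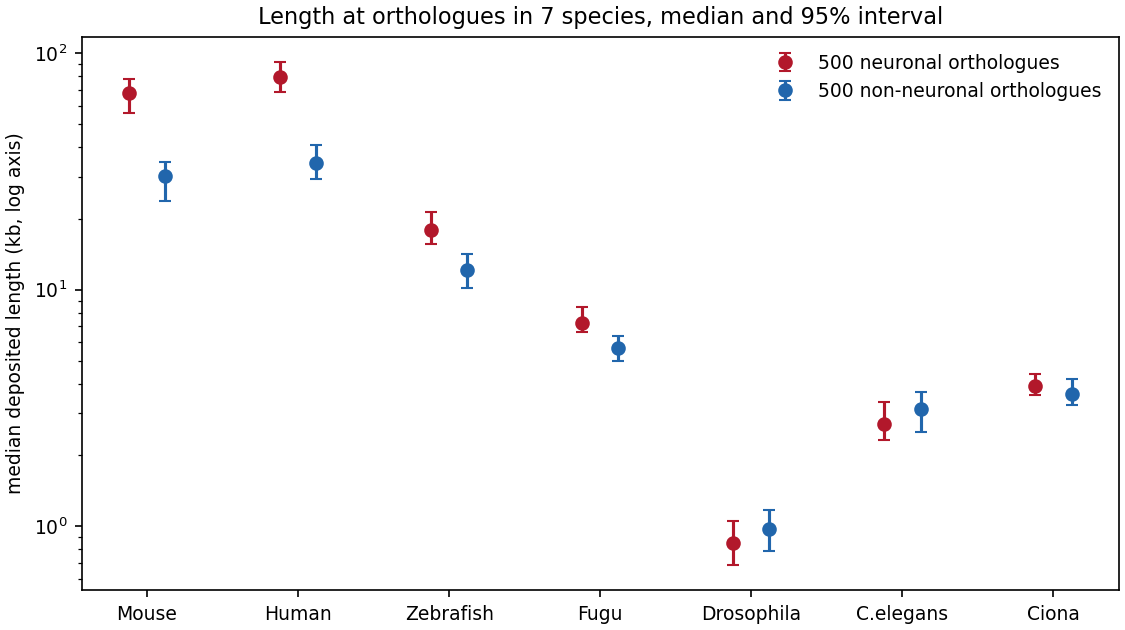
Points give the median intergenic length in kb (vertical axis, log scale) of 500 neuronal and 500 non-neuronal orthologues in 7 species (horizontal axis), with 95% bootstrap intervals. Neuronal orthologues are longer in mouse (68.0 against 30.3 kb) and human, and the intervals of both sets overlap in Drosophila, C. elegans and Ciona.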

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

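No test in this part was chosen after its result was seen. A difference between gene classes under the same contrast stood out for the orthologues, by a test of the difference itself that permuted the class over genes. The median log2 ratio of mouse to zebrafish length was 0.66 higher for neuronal than for non-neuronal orthologues (adjusted p = 0.0175, two-sided permutation test). For Fugu the difference was 1.15, for Drosophila 1.60, for C. elegans 1.53 and for Ciona 1.22, each with adjusted p = 1.5e-05. For human it was 0.06 and did not pass (adjusted p = 0.163). As a difference of means, the value was 0.31 for zebrafish (adjusted p = 0.552) and -0.30 for human (adjusted p = 0.402), and neither passed. Lengths listed at 0 enter such means as a log2 of 0 and can weigh heavily on them. Each class held 500 genes, and no explanation for these differences was tested.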

How the results depend on the processing

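Chosen only after the data were seen were the scaling without haemoglobin and mitochondrial genes, the minimum of 5 TPM, the other definitions of the interval, the subsets of the e13.5 MN class, the classes without genes in the stretches that hold no site, the better-scoring peaks at broad neuronal genes, the contacts beyond 5 kb of a start and as listed, the 2 other references for the Isl1 and Lhx3 table and the single gene per set of invertebrate lengths. Of 292 values under an alternative, 204 were kept, 61 without a test moved further, 10 gained and 7 lost their call, and 10 changed sign. Kept means the same direction and side of the threshold for a tested value, a share within its interval, a count without a test within 1.5-fold, and an unchanged log2 ratio of a single gene. Where no cause is named, the cause was not tested. Depth and replicate spread limit every expression count, since each group has a single column. No paired analysis was possible because the files combine the replicates of a group. For the same reason fits of the 2 groups alone, an adjusted p of 0.05 with no fold limit and leaving out replicates were not run; neither were a stricter score limit for contacts, which carry no score, and a reference matched on expression for the list named top500_pMN.

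With a pseudocount of 0.1 the genes lower in in vitro MN than in mESC went from 789 to 1891, and those higher and lower in e10.5 than in in vitro MN from 183 to 1078 and from 347 to 894; ratios of low values grow by construction. Quantile normalization gave 1932 higher and 1721 lower genes in e13.5 MN against e14.5 SN (3935 and 521 as deposited) and 276 higher and 228 lower in e10.5 MN. Scaling without haemoglobin and mitochondrial genes gave 1068 lower genes in e13.5 MN and 295 higher in e10.5 MN.

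Peak overlaps moved with every choice. A reciprocal overlap of 50% left 9.38% of in vitro MN sites in e10.5 MN (22.4% before) and 20.6% the other way (51.7%), 23.8% of e10.5 MN sites in e13.5 MN (37.8%) and 22.8% back (35.4%), and 27.2% of e13.5 MN sites in e14.5 SN (54.0%) and 16.1% back (31.6%). In the same order, the better-scoring 50% of peaks gave 23.8%, 53.7%, 36.5%, 34.5%, 47.9% and 28.2%, equal numbers of top peaks 39.3%, 41.5%, 37.0%, 36.2%, 40.7% and 40.1%, and sites beyond 5 kb of a start 24.4%, 52.4%, 38.4%, 34.6%, 53.5% and 31.95%. Shares of in vitro MN sites with Med1, H3K27ac and both were 6.96%, 4.24% and 1.99% with the reciprocal overlap, 16.3%, 13.1% and 10.1% with better-scoring peaks and 12.9%, 9.08% and 6.95% beyond 5 kb (17.2%, 13.8% and 11.2% before). The excess of sites open in 1 of 2 cell types at broad neuronal genes was 1.17 points with equal numbers of peaks (p = 0.151, permutation test).

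Interval lengths of the e10.5 MN, e13.5 MN, e14.5 SN and broad neuronal classes kept their call under each alternative. For the other neuronal classes only means of log2 values and other definitions of the interval were run, and their calls were kept. The mESC class, 3578 bp longer than other genes without passing, turned to a mean log2 difference of -0.0823, to -5357 bp with annotated gene starts and to -2205 bp over gaps, none past the threshold. Its enhancers went from a difference of 0 to -1 against genes matched on expression (adjusted p = 0.000117) and to 0.00292 per kb (adjusted p = 0.00423), and those of the list named top500_ESC from 1 to 0.00673 per kb. Contacts, whose medians were tied at 0, differed on the mean log2 scale by 0.68 in the e10.5 MN class, 0.54 in e13.5 MN, 0.24 in e14.5 SN, 0.27 in broad neuronal genes, 0.13 in the top500_ESC list and 0.45 in the top500_pMN list (adjusted p = 2.29e-05 each). Among genes with at least 1 contact the difference of medians was 1 in the e10.5 MN (adjusted p = 0.0028) and the e13.5 MN class (adjusted p = 0.00464). Taking progenitor anchors as listed lowered shared pairs to 7.46% of in vitro MN and 12.5% of progenitor pairs.

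For orthologues, the log2 difference between neuronal and non-neuronal length in Fugu went from 0.36 to 0.24 with a value in every species (adjusted p = 0.146) and to 0.44 as a mean of log2 (adjusted p = 0.104), and in zebrafish from 0.56 to 0.92 as a mean of log2 (adjusted p = 0.0781). In C. elegans it turned from -0.20 to 0.0689 with a value in every species and 0.0117 with 1 gene per set, never past the threshold. The ratio of mouse to human turned from -0.15 to 0.15 as a mean (p = 0.00485, permutation test) and 0.0926 after division by the median of each species (p = 1e-05, the smallest possible), and its class difference from 0.06 to -0.30 as a mean (adjusted p = 0.402). Lengths listed at 0, 73 in mouse and 144 in human, enter these means as a log2 of 0. With a value in every species the median ratio of mouse to human stayed negative, at -0.17. The class difference of mouse to zebrafish fell to 0.31 as a mean (adjusted p = 0.552). Division by the species median, which removes the difference between genomes by construction, left log2 ratios of mouse of 0.0914 to zebrafish, 0.0529 to Fugu and -0.30 to Drosophila.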

Other observations

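Chosen only after the result was seen were the comparison of e13.5 with e10.5 MN by gene list, the values of ribosomal protein genes and of stretches without open sites, the tests on gaps between gene bodies, the use of the fixed comparison on matched expression as a test of a cause, the quantile test over all members, the test of the 4 other lists, and the test of expression by contact.

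From e10.5 to e13.5, gene lists differed in how many members stood higher in MN, and no member of any list was more than 4-fold lower. Channel genes were more than 4-fold higher at e13.5 for 11 of 31 members compared (median log2 ratio 1.58), synaptic adhesion genes for 9 of 29 (1.58) and sensory neuron genes for 7 of 21 (1.32). Few or none were in the pan-neuronal (1 of 41, 0.55), axon guidance (1 of 27, 0.47), motor neuron identity (0 of 20, -0.03), Hox (0 of 28, -0.17), housekeeping (0 of 27, -0.17) and cell cycle lists (0 of 20, -0.77). Neural progenitor genes gave 1 of 20 (-0.97), interneuron genes 3 of 17 (1.00) and pluripotency genes 1 of 12 (-0.23). In the same pair, markers of endothelium were more than 4-fold higher for 8 of 8, of blood for 8 of 12, of mesenchyme for 9 of 10, of muscle for 5 of 7 and of glia for 2 of 11. These values have no test, since each cell type has a single column. Unlike the list medians of the other comparisons, they were not set against the median of all genes. No rescaling was run on them, so a difference of scale between the columns may enter them.

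Ribosomal protein genes differed by column. Their median was 2221 TPM in mESC, 1147 in in vitro MN, 935.5 in e10.5 MN and 574 in e13.5 MN, against 53 in e14.5 SN. Listed at 0 were 10 of them in e14.5 SN, 3 in e13.5 MN, 2 in e10.5 MN and 2 in in vitro MN, and a listed 0 is not read as absence in any of these columns. Open sites of sorted neurons were absent from 2 stretches where in vitro MN had 634 and 156 sites (0.394% and 0.0970% of its list), and the number of genes touching them was 55 and 85, with 44 olfactory receptor genes in the stretch on chromosome 17. A gene there, such as Lrrc4c with 379 open sites in in vitro MN, therefore has no interpretable count in the 3 sorted lists.

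Neuronal classes lay in longer intervals between neighbouring genes than other genes. The tables argue against gene body length as the whole cause, because the gaps between gene bodies were 3.90 times as long for e13.5 MN class genes as for others (adjusted p = 1.9e-05). They argue the same way against expression level, with a difference of 258868 bp against genes matched on expression (adjusted p = 1.25e-05, permutation test), and against counting protein-coding neighbours alone, with a ratio of 2.01 when all annotated gene types were neighbours (97003 against 48261 bp, p = 1e-05, the smallest possible). Biological explanations, such as room needed for regulatory elements, may hold but were not tested.

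Markers of blood, endothelium, mesenchyme, muscle and glia stood higher in e13.5 MN than in e14.5 SN, although MN had been sorted by a Chat reporter, which should leave other cells out. After quantile normalization 71.4% of the members that were more than 4-fold higher (25 of 35) stayed so. That share lay between the bounds set beforehand. A further test over all 47 members gave a median log2 ratio of 2.41 (95% interval 1.43 to 3.35, 42 above 0). It argues against the scale of the e14.5 SN column as the whole cause only if the listed zeros are real. Listed at 0 in 1 of the 2 columns were 4 of 8 endothelial, 9 of 12 blood and 2 of 10 mesenchymal members. So were 4 of 7 muscle and 5 of 10 glial members. Quantile normalization cannot restore a missing estimate, so missing estimates in e14.5 SN stay open. RNA from blood cells is a candidate source, since 92.3% (12 of 13) of measured erythroid genes other than haemoglobins were at least 2-fold higher in e13.5 than in e10.5 MN, among them the erythrocyte anion exchanger Slc4a1 at 95 TPM against 0 and Slc25a37 at 40 against 9, while several others lay near the floor. Members of the other 4 lists had a median log2 ratio of 3.01 (interval 1.88 to 3.60, 30 of 36 at least 2-fold higher), in line with RNA from such cells, but 21 of the 48 members of the 5 lists are also listed at 1 TPM or more in in vitro MN and 0 belong to another list. A difference between motor and sensory neurons, or between the days, stays open and was not tested.

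Open sites of in vitro MN with Med1 or H3K27ac beyond 5 kb of a start were found in e10.5 MN in 64.6% of 20031 cases, against 17.3% of 113004 without a mark. The tables argue against site width as the whole cause, since the difference was 43.9 points (95% interval 43.2 to 44.7) among sites matched on width. They argue in the same way against peak score, with 23.1 points (22.2 to 24.0) among sites matched on score, although score took up more of the difference. That marked enhancers may be kept more often in embryonic MN is a hypothesis that was found and tested on the same lists. Sites with both marks, 1 mark and neither were found in e14.5 SN in 49.5%, 45.9% and 26.2%, so the pattern was not particular to MN.

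A hypothesis was that contacts of e13.5 MN class genes run across fewer starts of other protein-coding genes, the only genes counted as skipped. It held for this library: 19.8% of 673 contacts of 184 class genes skipped a gene against 45.0% for other genes, a difference of -25.2 points (p = 2e-05, permutation over genes). A second one, that these contacts are longer, also held, with a median of 143 against 107 kb, a difference of 36.6 kb (95% interval 10.2 to 60.5, p = 0.00309, permutation test). The same differences were -23.2 points and 22.0 kb (adjusted p = 0.0496, permutation test, but with a 95% interval of -2.16 to 42.5 that includes 0) for the e10.5 MN class, -21.8 points and 42.6 kb for the e14.5 SN class and -21.7 points and 41.6 kb for broad neuronal genes, whereas mESC class contacts skipped a gene more often by 23.3 points (adjusted p = 0.00257). The distance of mESC class contacts differed by -34.1 kb (95% interval -74.8 to -1.39) and did not pass (adjusted p = 0.102, permutation test). The longer intervals of neuronal genes could account for both differences of the neuronal classes, which was not tested. Genes with contacts in in vitro MN alone had a median log2 ratio of in vitro MN to mESC of 0.72 (1529 genes measured), those with contacts in progenitors alone 0.49 (1301) and those with both 0.76 (948). The difference of the first pair was 0.23 (95% interval 0.13 to 0.32, p = 5e-05, permutation test). Every measured gene with a contact in in vitro MN stood at 2 TPM or more there. Olig2, with contacts in progenitors alone, stood at 1 TPM. Selection on in vitro MN expression may thus enter this ratio, so the difference is not independent evidence.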
